A study of Drosophila melanogaster with 4 samples.

How the data were processed

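H3K23ac ChIP-seq of wild-type Oregon-R embryos aged 14 to 16 hr was analysed from 3 lists of enriched regions, 1 per ChIP replicate and 1 combined list for the series. Per the labels, embryos were crosslinked with 1.8% formaldehyde, chromatin was immunoprecipitated with an antibody against H3K23ac, and each of the 2 input libraries served as the input for the list of 1 replicate. Values of the input libraries themselves were not used here. Bowtie 0.12.7 is named per the submitters' processing notes, without its role or settings. Coordinates are on FlyBase release 5, per the file headers, which also give the chromosome lengths used here. The region caller, its threshold, and whether the combined list was made by pooling reads or by merging regions are not given in the sources used here. Each replicate list is tied to 1 sample, so regions are taken as called per sample.

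The deposited score is 1 number per region on a log2 scale. The file headers do not define it, and the scale was found from the values: for 100% of the regions of each list, 2 raised to the difference of scores was a ratio of whole numbers up to 20000 within a relative tolerance of 1e-12, whereas natural and decimal logarithms gave this for at most 0.0392%. With 1 constant per list (0.712, 0.540 and 0.622 for replicate 1, replicate 2 and the combined list, each the constant that gave the smallest whole numbers), 100% of scores were the log2 of a constant times a whole-number ratio. What the numerator and the denominator count is not stated, and the smallest whole numbers need not be the original ones, so no read depth was derived and the depth is unknown. The score was used to rank and compare regions within a list, and in rank correlations between lists. A list of regions gives no signal outside its regions, so that a missing region means only that the authors' threshold was not passed. The narrowest region was 1301 bp wide in both replicate lists and 1001 bp in the combined list.

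Overlap in bases was measured as the Jaccard index and tested by circular shifts of 1 list within each chromosome, 100000 shifts at a resolution of 100 bp, one-sided. This keeps region widths and spacing. Region shares count a region with at least 1 shared base, with 95% Wilson intervals, and those between the replicates are given beside the mean of 1000 shifts. Score agreement used Spearman's rho over region pairs matched by largest overlap, one to one, with an interval from 1000 bootstrap resamples. The X was set against the 4 large autosomal arms by the ratio of covered shares, by the difference of median scores, and by a two-sided permutation test with 100000 permutations of the labels of 1-Mb windows. Windows with fewer than 5 regions gave no median score, and the 1 Mb nearest each centromere was left out of this test. Here and below this is the 1 Mb at the centromere-side end of the arm sequence, since heterochromatic scaffolds are separate. Intervals on density ratios come from 2000 resamples of windows. Means ± SD are over the 2 replicates. The comparisons of the replicates with each other and with the combined list, and the coverage by arm were fixed before the data were examined, with a first set of alternatives. Further alternatives, the X tests by window, the bands near centromeres, the 250-kb windows and the comparisons by width or score quartile were chosen after seeing the data.

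The overlap test and a stricter form of the score pairing were tested on simulated data with the region numbers of the large arms, 10252 and 7396. Simulated regions were placed uniformly at random within each arm, so the clustering of the real lists was not covered. With no planted sharing 0 of 20 simulations gave p under 0.05, and with 10% or 50% planted sharing 20 of 20 did. A planted score correlation of 0.6 was returned as 0.595 and 0.585 for planted copies with the same coordinates, paired by nearly full reciprocal overlap. The looser pairing by any overlap, used for the replicates, was not simulated. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

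Regions are named by a rule set in advance for the case without a matching annotation: the 10 highest-scoring combined regions that overlap a region of both replicates, and the 5 longest stretches covered in both. Genes are not named. The gene table at hand is on Release 6 of the genome, and coordinates were not converted between releases. For this reason the planned tests of transcription start sites, of genic features and of 14 gene lists were left out. The alternatives tried were at least 50% coverage for a shared region, regions above each list's median score, equal numbers of regions, merging of regions under 1000 bp apart, the large arms alone, and leaving out each replicate. The number of columns left unused for lack of a sample was 0.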

Results

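Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map H3K23ac, the acetylation of a lysine in the N-terminal tail of histone H3, in *Drosophila melanogaster* embryos. The embryos were of the wild-type laboratory strain Oregon-R and 14 to 16 hr old, a late stage of embryogenesis at which the organs are being formed. The series held 4 samples, of which 2 were H3K23ac ChIP replicates and 2 were input libraries of chromatin without immunoprecipitation. Enriched regions were analysed from 3 lists, 1 for each ChIP replicate and a combined list of the series. Replicate 1 had 10281 regions covering 23.1 Mb in all, and 19.3% of the 5 large chromosome arms. Replicate 2 had 7422 regions covering 16.2 Mb in all, and 13.6% of these arms, so that replicate 1 covered 1.42 times as many bases. The combined list had 18064 regions covering 47.5 Mb in all, and 39.8% of these arms. Median region widths were 1838, 1787 and 1855 bp, respectively. Each region carried 1 score assigned by the authors, on a log2 scale, with medians of 0.67 in replicate 1, 0.66 in replicate 2 and 0.46 in the combined list. The number of reads behind each list was unknown. No label states whether the replicates came from separate embryo collections, so that differences between them may be technical. No p-value here measures variation between samples: each comes from positions, windows, arms or regions within these lists. Intervals on shares cover counting error only. Positions are given on FlyBase release 5.

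H3K23ac regions of the replicates overlapped far more than randomly placed lists would, although most covered bases were found in 1 replicate only. Bases covered in both replicates came to 10.1 Mb and bases covered in either to 29.2 Mb, a Jaccard index (shared over total bases) of 0.347. The shared bases formed 6000 stretches with a median length of 1523 bp, of which 86 reached 5 kb and 7 reached 10 kb. The longest, of 13232 bp, lay on 2L at 1405885 to 1419116, followed by 12815 bp on 2R at 9343983 to 9356797 and 12079 bp on 2R at 3061484 to 3073562. The remaining members of the 5 longest were 2L 6182279 to 6193947, of 11669 bp, and 2R 20686862 to 20698050, of 11189 bp. When 1 list was shifted at random along each chromosome the Jaccard index averaged 0.0898 and reached at most 0.143 in 100000 shifts. The observed value was 3.86 times that average (one-sided permutation test, p = 1e-05, the smallest these shifts can give). With shifts of 20 to 200 kb only, the average was higher, 0.111, and the observed value was 3.12 times it.

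**Figure D1:**
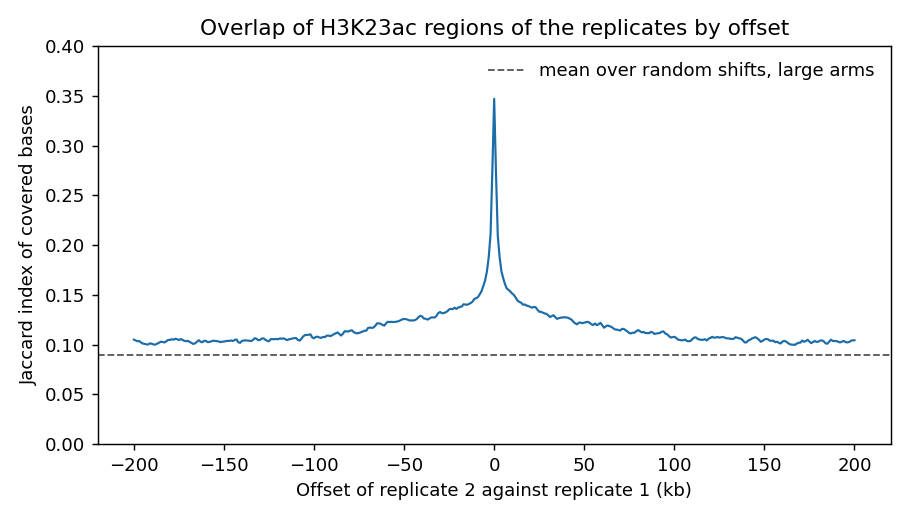
Jaccard index of the bases covered in replicate 1 and replicate 2 on the 5 large arms (y axis) when replicate 2 is moved by the offset on the x axis, in kb. The solid line peaks at 0.347 with no offset, and the dashed line marks the mean over random shifts, 0.0900.

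Counted as regions, 5397 of the regions of replicate 2 (72.7%, 95% Wilson interval 71.7 to 73.7%) shared at least 1 base with replicate 1, against 34.5% on average and at most 40.4% in 1000 shifts. In the longer list of replicate 1, 5324 regions (51.8%, interval 50.8 to 52.7%) shared a base with replicate 2, against 24.9% on average and at most 31.6% after shifting. Wide regions were shared most often. On the large autosomal arms, 33.3% of the narrowest quartile of replicate 1 (median 1391 bp) and 82.5% of the widest (median 3367 bp) were found in replicate 2. In replicate 2 these shares were 55.3% and 92.4%. A wide region also meets more bases by chance, and the shift averages were not computed by width. By score, the shares in the lowest and highest quartiles were 45.3% and 65.5% in replicate 1, and 60.7% and 83.6% in replicate 2. These score quartiles also differed in width, with medians of 1532 and 2671 bp in replicate 1 and of 1512 and 2576 bp in replicate 2. On the X the shares of replicate 1 from the lowest to the highest score quartile were 33.8%, 41.8%, 35.6% and 51.3%. Those of replicate 2 rose steadily, with 59.5%, 65.9%, 77.0% and 81.9%.

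Among combined regions that overlapped a region of both replicates, the highest score belonged to X 1891218 to 1894734, at 1.07 in the combined list, 1.49 in replicate 1 and 1.12 in replicate 2. Next came 2R 3104574 to 3110712, with a combined score of 1.04, X 19761958 to 19766540, with 1.03, and 3L 11951902 to 11958542, with 0.99. The regions 2R 8885688 to 8892650 and 3R 24407200 to 24410814 both scored 0.97 in the combined list. They were followed by X 2021164 to 2026704 and X 19670566 to 19677728, both at 0.95, and 3L 867030 to 870904, at 0.94. The last of these 10 regions, at 0.92, lay on the unplaced scaffold U at 5570992 to 5573462. Of the 10, 4 were on the X, 2 each on 2R and 3L, and 1 each on 3R and U. All 10 were found in both replicates by the way they were chosen. Their positions are those of the combined list, in which they ranked from 30 to 53, since the higher-ranked regions did not overlap both replicates.

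Over all 4946 pairs of overlapping regions the scores of the replicates were moderately correlated (Spearman's rho 0.416, 95% bootstrap interval 0.393 to 0.439). This correlation is across regions, which are not independent replicates, and has no p-value. The amount of covered sequence in windows of 100 kb had a rho of 0.887 between replicates across 1189 windows, a measure that sums over many regions and is not comparable with the one for scores of single regions.

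The combined list contained nearly all bases of both replicates and a large set of regions beyond them. It covered 98.1% of the bases of replicate 1, 98.4% of those of replicate 2 and 99.99% of the bases found in both. Of its regions, 4415 (24.4%, 95% Wilson interval 23.8 to 25.1%) overlapped a region of both replicates, 5717 (31.6%, interval 31.0 to 32.3%) overlapped a region of 1 replicate and 7932 (43.9%, interval 43.2 to 44.6%) overlapped neither. Of the regions found in 1 replicate, 4139 were found in replicate 1 and 1578 in replicate 2. Regions found in both replicates were wide and high-scoring, with a median width of 4111 bp and a median score of 0.54. The medians were 1995 bp and 0.45 for regions in 1 replicate, and 1317 bp and 0.43 for regions in neither. In bases, 21.3% of the combined list was covered in both replicates, 38.6% in 1 and 40.1% (19.1 Mb) in neither. When at least 50% of a combined region had to be covered, the share in both replicates was 14.5%.

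H3K23ac regions were unevenly spread over the chromosomes. Arm 2R had the highest covered share, 20.7% ± 4.28 (SD, n = 2), followed by 3R with 18.4% ± 4.27, 3L with 16.1% ± 3.69 and 2L with 15.5% ± 3.17. The X followed with 11.4% ± 4.91 (14.9% in replicate 1 and 7.93% in replicate 2). Chromosome 4, the small and largely heterochromatic dot chromosome, had 3.03% ± 0.0435, with 22 and 23 regions, and 10.1% in the combined list. Replicate 1 covered more than replicate 2 on each of the large arms. In both replicates 2R ranked first, the X last among the large arms, and chromosome 4 below all of them. The 8 scaffolds of heterochromatic and unplaced sequence (48.3 Mb) held 7 regions of replicate 1, 3 of replicate 2 and 32 of the combined list, covering 0.0218%, 0.00934% and 0.0925% of their length. The Y scaffold and the largest unplaced scaffold held 0 regions in each list. Whether reads could be placed on these scaffolds or on chromosome 4 was not examined, so low coverage there means only that few regions were called. With arms as the units no test was run, because 1 X against 4 large autosomal arms gives no exact one-sided p below 0.2.

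**Figure D2:**
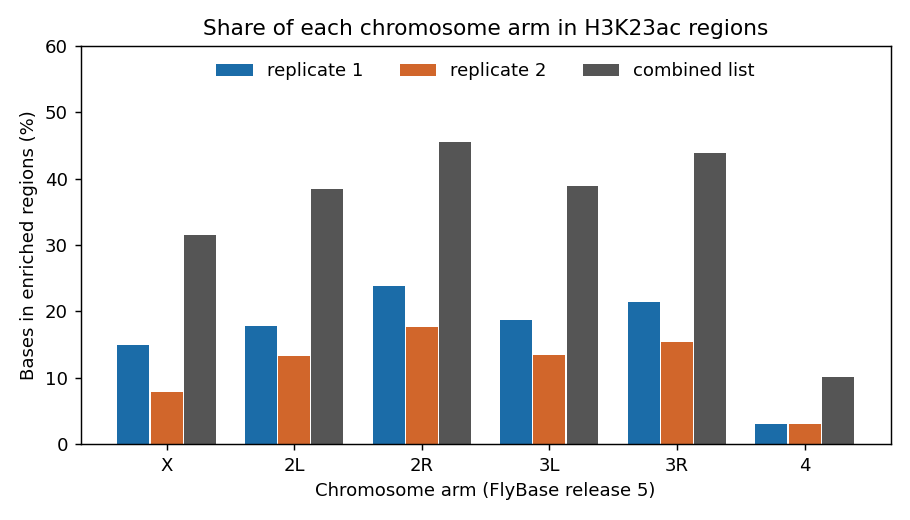
Percent of the bases of each chromosome arm (x axis) that lie in enriched regions (y axis) in replicate 1, replicate 2 and the combined list, shown as bars that each stand for 1 list. The X is the lowest of the large arms in all 3 lists, and chromosome 4 stays at or below 10.1%.

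The X chromosome, which is present once in males and in a pair in females, carried fewer but higher-scoring regions than the autosomes. Its covered share was 0.632 ± 0.140 (SD, n = 2) of that of the large autosomal arms, 0.731 in replicate 1 and 0.532 in replicate 2. It had 69.6 regions per Mb against 89.97 in replicate 1, and 40.4 against 67.2 in replicate 2. The median score on the X exceeded that of the autosomes by 0.11 ± 0.026 on the log2 scale (SD, n = 2), a 1.08-fold higher ratio, with 0.13 in replicate 1 and 0.091 in replicate 2. Across windows of 1 Mb outside the 1 Mb nearest each centromere, 21 on the X and 91 on the autosomes, mean coverage was 15.3% against 20.9% in replicate 1 and 8.33% against 15.2% in replicate 2. A permutation test of the window labels gave two-sided p = 0.00062 and 2e-05, or 0.00062 and 3e-05 after Benjamini-Hochberg adjustment over 6 tests. The same permutation test of window medians of the score gave p = 2e-05 in each replicate, the smallest it can give (adjusted p = 3e-05). Windows of an arm are neighbours and not replicates, so this test compares windows within these lists and not independent arms or embryos. Among regions above each list's median score the coverage ratio was 0.953. Regions above the upper quartile of autosomal scores were denser on the X, by 1.98 times in replicate 1 (95% bootstrap interval 1.62 to 2.42) and 1.50 times in replicate 2 (1.11 to 1.96).

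**Figure D3:**
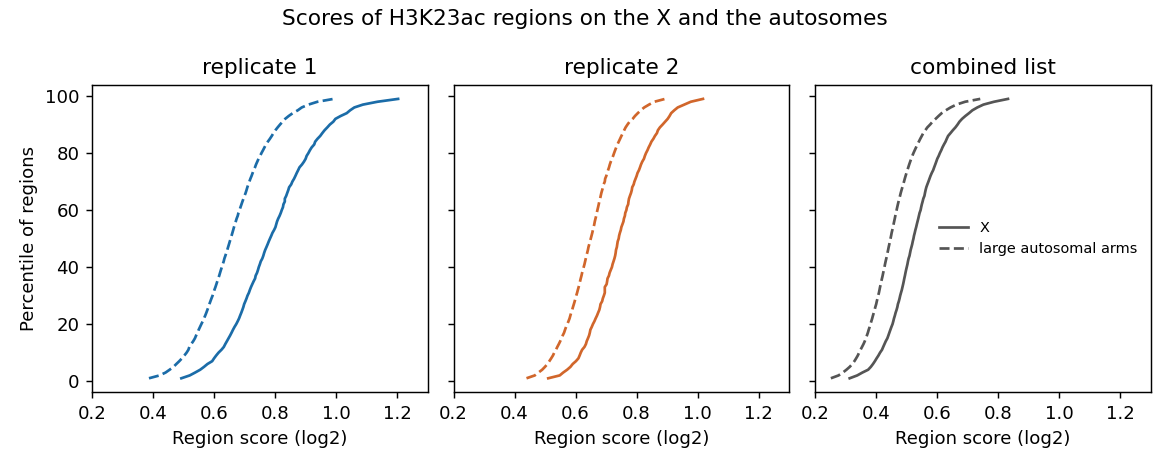
Percentile of regions (y axis) against region score on the log2 scale (x axis) for the X (solid lines) and the large autosomal arms (dashed lines), in 1 panel per list. The X curve lies to the right in each panel, with medians of 0.78 against 0.65 in replicate 1, 0.74 against 0.65 in replicate 2 and 0.52 against 0.45 in the combined list.

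Along the arms, regions were sparse at the centromere-side end of most arm sequences and dense in particular windows. Separate scaffolds hold heterochromatic sequence of these chromosomes. The end of an arm sequence therefore need not lie at the centromere, or equally near it on each arm. The 1 Mb at this end of 2R and of 3L held 0 regions in both replicates, and that of 2L was covered to 3.36% and 2.88%. On 3R the corresponding 1 Mb was covered to 28.7% in replicate 1 and 26.4% in replicate 2, above the rest of the arm (21.1% and 14.9%). Over the 5 arms the proximal 1 Mb averaged 7.18% and the remainder 16.9%, lower in 4 of 5 arms. An exact two-sided sign permutation test over 5 arms gives no p below 0.0625 and so could not decide on this difference (p = 0.1875). The most densely covered window of 250 kb lay on 3L between 22.25 and 22.5 Mb, with 60.6% ± 5.74 (SD, n = 2) of its bases in regions. The windows 3R 6.25 to 6.5 Mb with 52.4% ± 1.73 and 2R 15.75 to 16 Mb with 48.7% ± 4.05 came next, and were chosen after their values were seen. Of 479 such windows 14 held no region in either replicate, 6 of them on 3L and 5 on 2R. Whether reads could be placed in these windows was not examined.

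**Figure D4:**
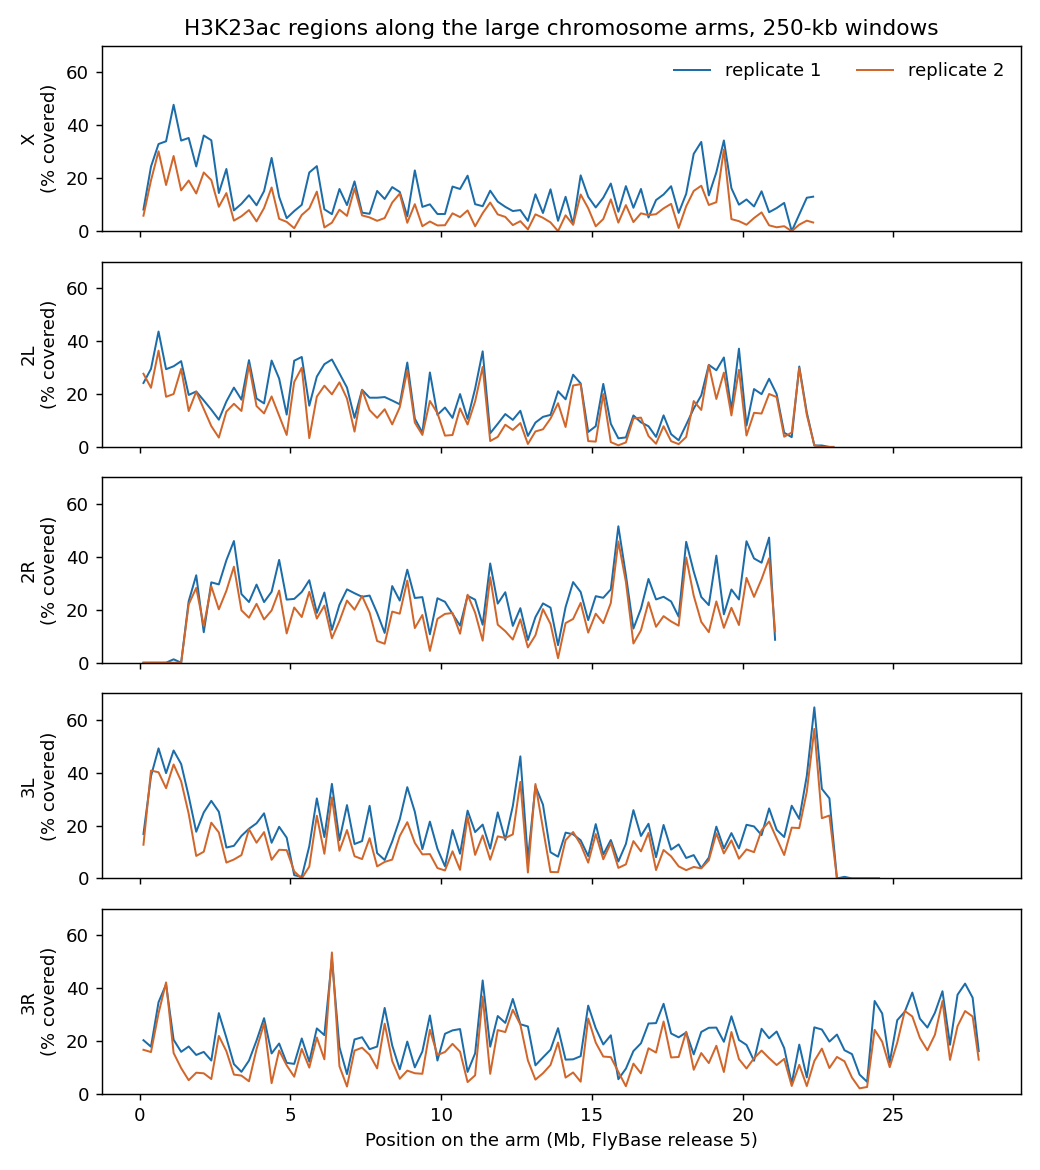
Percent of bases in enriched regions (y axes) in windows of 250 kb along the 5 large arms (x axis, position in Mb), with 1 line per replicate. Both lines fall to 0 at the centromere ends of 2R and 3L, at the left and the right, and reach their highest mean, 60.6%, on 3L between 22.25 and 22.5 Mb.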

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

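The alternatives for shifts of 20 to 200 kb only, without the proximal 1 Mb of each arm, bases covered in both replicates, autosomes or X alone for the score correlation, and all those for the X score difference were chosen after seeing the data. The overlap in bases stayed above all shifts under all 6 alternatives (permutation p = 1e-05 in each), with Jaccard indices from 0.261 to 0.358. Of the 24 alternative values of the other results, 15 moved beyond their replicate SD or their interval and 5 did not. The remaining 4 leave out 1 of 2 replicates, which by construction stays within the SD and says nothing about stability. The share of regions shared depended on the setting: with at least 50% of the region covered it was 42.0% for replicate 1 and 62.4% for replicate 2, among regions above each list's median score 39.9% and 56.5%, and with the same number of regions, highest scoring, 54.1% and 57.8%. With regions under 1000 bp apart merged it was 74.0% for replicate 2. The first of these asks for more overlap, and the equal-number setting shortens only the list that replicate 2 is held against, so these falls follow from the settings. The second shortens the list to be met, but the effect of this was not separated from that of imperfect score agreement. At equal numbers replicate 1 lost only its lowest-scoring regions against an unchanged list. Its rise means that the regions left out were shared less often. The cause of the rise after merging was not tested. The score correlation was 0.492 with at least 50% reciprocal overlap, 0.361 on the large autosomal arms only and 0.356 on the X only, both of the latter below the pooled 0.416. With at least 50% of the region covered, 14.5%, 36.0% and 49.6% of combined regions were in both replicates, in 1 and in neither. The X over autosome coverage ratio ranged from 0.532 to 0.731 on leaving out each replicate and was 0.756 in the combined list, 0.508 for bases covered in both replicates and 0.953 among regions above each list's median score. The X score difference ranged from 0.091 to 0.13 on leaving out each replicate and was 0.075 in the combined list; the cause was not tested. No paired analysis was possible because values of the input libraries were not used here and only the ChIP samples have lists. Not run for want of an annotation of the files' build were the alternatives for genes marked at the transcription start site, for genic features and for the 14 gene lists. Depth is unknown, so that its effect on the differing list lengths could not be measured.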

Other observations

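Outside the 1 Mb nearest each centromere, long stretches without any region in the 3 lists were most numerous on the X and on 2L. There were 39 such gaps of at least 50 kb, 15 on the X, 10 on 2L, 6 on 2R, 5 on 3L and 3 on 3R, together 3.10 Mb or 2.72% of this sequence. The longest of these gaps were 3L 23025979 to 23251137 (225 kb), 2L 21377723 to 21578605 (200.9 kb) and 2R 2229271 to 2389411 (160 kb). All 3 lay toward the centromere-side end of their arm sequence, which is at 24543557 on 3L, at 23011544 on 2L and at the start of 2R. Read placement in the gaps was not examined, so a gap means only that no region was called there.

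All tests of the patterns that follow were chosen after seeing the data. Those of region density, of numerators per kb and of the highest-scoring combined regions were chosen after their own result was seen, and those by region width, of edges and of the threshold before it. No biological explanation was tested for any of them, since the design has 1 strain and 1 stage.

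The X had fewer but higher-scoring regions. A higher bar on the X over the same underlying scores, with equal scatter, allows densities up to the autosomal one at any score. But the density above the autosomal upper quartile was 1.74 times that of the autosomes on average, with both intervals above 1. Above the autosomal median it was 1.29 times (1.07 to 1.55) in replicate 1 and 0.982 times (0.761 to 1.22) in replicate 2. Scores on the X may scatter more if they rest on fewer tags, so these densities cannot decide on a higher bar joined with wider scatter. The 5th percentile of scores was higher on the X too. It was 0.567 against 0.466 in replicate 1 and 0.583 against 0.500 in replicate 2. Chance inflation confined to narrow regions would fade in wide ones. But the X excess in the widest quartile was 1.21 times that in the narrowest on average over the replicates (1.31 and 1.12). In the combined list it was 0.926 times. Width is not a tag count, so this comparison cannot decide on inflation by low counts in regions of every width. Fewer sequenced tags on the X remain a candidate explanation for the fewer regions: the numerators of the smallest whole-number ratios behind the scores, per kb of region, were 0.721 times those on the autosomes (0.709 and 0.733, intervals 0.686 to 0.729 and 0.705 to 0.758), and the denominators, compared first, 0.638 and 0.672 times, if these numbers follow tag counts. If male and female embryos were mixed, fewer tags on the X would follow from its copy number, whether or not they limit the calls. These values therefore cannot decide whether fewer tags explain the fewer regions. The higher scores may also come from a stronger acetylation of marked X chromatin, which these lists do not test. The 1 constant per list adds the same amount to every score and so cancels in the X score difference.

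In the combined list 19.1 Mb lay outside both replicate lists. Wider edges of known regions could account for only part of it, since 38.4% of these bases were in combined regions that overlapped a replicate region. Merging both replicate lists would leave no combined region outside them. The 7932 outside regions therefore argue against a list made by merging these lists alone. Pooling of reads was not tested. Median numerators per kb on the autosomes were 245 in the combined list, against 121 in replicate 1 and 147 in replicate 2. The denominators were 110, against 53.2 and 50.1, with common factors removed in all of these. A lower threshold that admits weaker regions stays open. The median score of the 7932 outside regions minus that of the other combined regions was -0.058 (95% interval -0.060 to -0.054), but the other regions had passed a replicate's own threshold and were wider (median 2643 against 1317 bp), so a lower score outside follows from the choice of groups whatever the cause. Of the outside regions 48.0% were narrower than 1301 bp, the narrowest width in the replicate lists.

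The 20 highest-scoring regions of the combined list, with scores from 1.41 to 3.01, were 1001 to 1193 bp wide, and 6 lay on heterochromatic or unplaced scaffolds. All 20 were absent from both replicate lists, but so were 93.3% of the 2964 other combined regions as narrow, so that their absence does not set them apart from regions of their width. For their high values, scores that rest on few sequenced tags are a candidate explanation, as the top value corresponds to a ratio of 13 to 1. Of the 20, 9 had a numerator at or below the 5th percentile of those 2964 regions (exact binomial test, one-sided, p = 2e-07), with a median of 25 against 222. These ratios and numerators are in smallest whole numbers, with common factors removed, so a small numerator need not mean few tags. Denominators were compared first, with 18 of 20 at or below that percentile, but a high ratio lowers the denominator by itself.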
